A study of Tetradesmus deserticola with 10 samples.

How the data were processed

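RNA was sequenced from 10 libraries of cultured cells of the desert green alga Tetradesmus deserticola (named Acutodesmus deserticola by the submitters), strain Sni-2, in 5 stages of a drying and rewetting course with 2 libraries per stage. Per the labels' protocols, ribosomal RNA was removed during library preparation with commercial and custom oligos. The labels do not say whether the 2 libraries of a stage came from separate cultures. The p-values therefore measure the spread between these libraries, which may be technical. The stage of each library was taken from its stage label and the replicate number from its title. The columns of the tables carry the prefix Sdes where the titles carry Ades, and each column was matched to the title with the same number and time code.

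The authors deposited expected counts, not normalized, and a second table of TMM-normalized expression signal for the same 20783 assembled genes. Per the submitters' processing notes, CASAVA 1.4, Trimmomatic 0.35, Bowtie2 2.2, RSEM 1.2.28 and DESeq2 were used; the role and order of each are not given in the sources used here. The row identifiers have the form that the Trinity assembler writes, and the column names mark the rows as plant genes. How the assembly was built and how plant genes were separated from other sequences are not given in the sources used here. RSEM estimates how many reads came from each gene, and between 2.59% and 4.58% of the values in a library were not whole numbers, which arises when a read matches several assembled genes and is divided among them. The deposited signal is corrected for gene length and library; whether it was TPM or FPKM before TMM is not given in the sources used here. The deposited signal was used for the relative length of each gene, for which counts were divided by signal, and for an alternative test.

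The files pair no identifier with a gene name, and no genome or annotation was used here. A gene is therefore given by its assembly identifier, without position, annotation or function. The gene lists fixed beforehand (photosynthesis, chaperones, late embryogenesis abundant proteins and others, including sequences of bacteria or fungi) could not be matched to any row, so no list was tested. The rule fixed beforehand named, per comparison, the 2 genes with the largest rise and the 2 with the largest fall among those with an adjusted p under 0.05, an absolute log2 fold change of at least 1, a mean of at least 50 counts over the 4 libraries and no overlap between the libraries of the 2 stages.

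Expected counts were rounded to whole numbers. Genes with too few counts for a test were removed with edgeR's filterByExpr at its minimum count of 10, which left 9856 genes holding 98.3% of all counts. Counts were scaled with TMM factors and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) in one fit over all 10 libraries with a term per stage, which leaves 5 residual degrees of freedom; p-values were adjusted by the Benjamini-Hochberg method within each of 7 comparisons. Standard errors of log2 fold changes were taken from the fold change and its F statistic. The common dispersion corresponded to a coefficient of variation of 28.6% between libraries of a stage. An exact two-sided permutation test of 2 against 2 libraries cannot go below p = 0.333, so no such test was made of single values, and chance alone leaves 33.3% of genes without overlap between 2 and 2 libraries. Where a stage held 0 counts in both libraries, the fold was bounded with 3 counts per library, and with 1 to 3 counts the ratio is given with its exact 95% Poisson interval. Poisson intervals and limits cover counting error only, since the reads carry no molecular identifiers here. Binomial intervals on shares of genes treat genes as independent, which they are not, and leave out the spread between libraries.

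Libraries held between 644705 and 1917825 counts over all genes. For scaling, library totals were taken over the genes tested, which are somewhat smaller. On that basis 3 counts corresponded to between 1.07 and 4.70 CPM (a gene's count relative to the TMM-scaled library total), highest in the Dry libraries. Relative to library totals without TMM they corresponded to between 1.59 and 5.0 CPM, highest in the Rehydrated libraries. On simulated data with 50 changed genes per fold size among 9856, the same fit recovered 8% of genes changed 2-fold, 58% of those changed 4-fold and 86% of those changed 8-fold for Early vs Hydrated, with 13 false calls. For Dry vs Hydrated it recovered 2%, 42% and 60%, with 5 false calls. The 13 false calls for Early vs Hydrated stood beside 4, 29, 43 and 43 genes recovered at 2-, 4-, 8- and 16-fold. Few genes changed in these simulations, whereas 4394 were called in the measured Dry vs Hydrated comparison. The share of changed genes affects the adjusted threshold, so these rates need not hold for the measured data. Libraries of one stage differed by more than sampling noise in every stage, with a chi-square per degree of freedom between 10.0 and 33.4, so none was treated as a repeat deposit.

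Comparisons that share libraries share their chance values. Overlaps between them were therefore set beside 20 simulated data sets without any difference between stages, in which at most 4 genes were called in a comparison, and beside the overlap of independent lists; after the data were examined, they were also counted with one comparison fitted against each Hydrated library alone. The alternatives planned before the data were examined were DESeq2 1.42.0, RLE factors, library totals without TMM, no count filter, a mean of at least 50 counts, the replicate number as a block, fits of only the 2 stages compared, limma 3.58.1 on the log2 of the deposited signal plus 1 or 0.1, a fold-change threshold, removal of the 100 most abundant genes and removal of each library in turn. After the data were examined, 3 were added, namely removal of 2 libraries in doubt, TMM factors from genes with a mean of at least 50 counts, and the genes called the same way under 4 scalings (TMM, RLE, library totals and the added TMM factors).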

Results

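The transcriptome of the desert green alga was sampled at 5 stages of drying and rewetting. Drops of 40 µL from cultures grown for 6 weeks were collected at once (Hydrated), 2.5 h into drying at a volume loss of 25% (Early), 7.5 h into drying at a volume loss of 60% (Late), and as fully flattened spots about 24 h after the start, kept in the drying chamber for a further 11 h (Dry). The fifth stage was collected 1 h after water was added back (Rehydrated). Each stage had 2 libraries. No drops kept wet for the same hours were among them, so drying and rewetting cannot be told apart from elapsed time in these comparisons. The Hydrated libraries held 1917825 and 1398635 counts, the Early libraries 1619077 and 1510141, the Late libraries 1162221 and 1880952, the Dry libraries 1453220 and 1594106, and the Rehydrated libraries 644705 and 826632. The median gene had between 1 and 6 counts in a library, so changes of weakly expressed genes could be detected only where they were large.

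At equal depth, fewer genes were detected in the Dry libraries than in any other library. With all counts kept, Dry replicate 2 had 14789 genes and Late replicate 1 had 14474. At an equal depth of 644686 counts, 16698 ± 1481 genes (SD, n = 2) were detected in Hydrated, 13498 ± 1109 in Early, 12609 ± 457 in Late and 10539 ± 177 in Dry. In Rehydrated the number was 17972 ± 2104, with 19459 genes in replicate 1 and 16484 in replicate 2. The 1000 most abundant genes of each library took 80.3% ± 1.17 of the counts in Hydrated, 86.7% ± 3.29 in Early, 88.8% ± 2.84 in Late, 94.0% ± 0.785 in Dry and 79.0% ± 7.21 in Rehydrated. The 100 most abundant genes took 53.0% ± 0.134 in Hydrated and 67.7% ± 1.58 in Dry, against 59.5% ± 8.51 in Early, 66.3% ± 5.49 in Late and 49.5% ± 5.55 in Rehydrated. For the 10 most abundant genes the shares were 27.3% ± 0.615 in Hydrated, 30.6% ± 10.6 in Early, 39.0% ± 6.48 in Late, 34.5% ± 2.18 in Dry and 18.6% ± 2.43 in Rehydrated. Both Dry libraries lay below all others in genes detected at equal depth and above all others in the share of the 1000 most abundant genes. No test was made of these values.

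**Figure D1:**
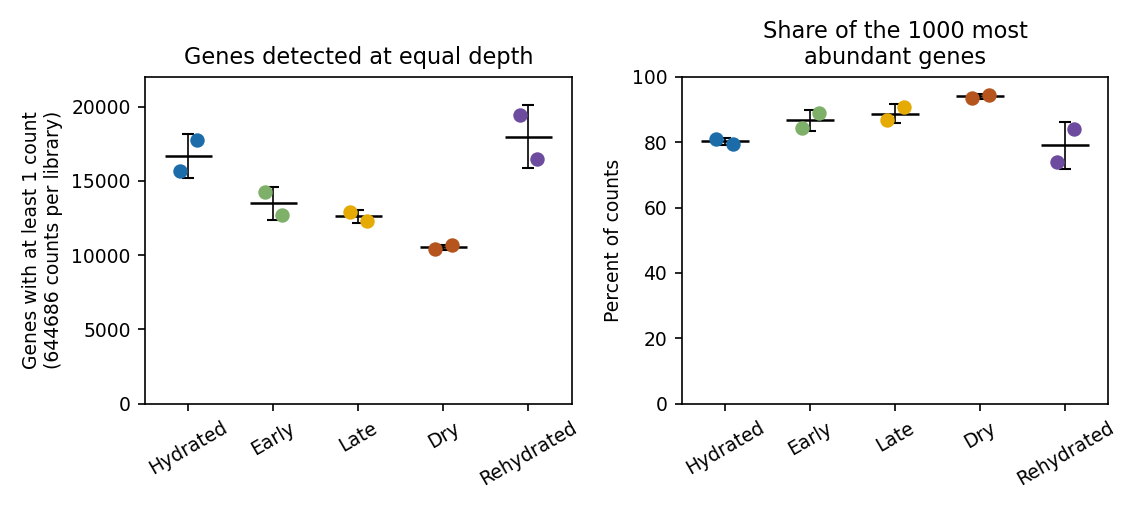
Genes with at least 1 count when every library is thinned to 644686 counts (left, number of genes) and percent of counts held by the 1000 most abundant genes of each library (right), by stage. Points are libraries, lines are means and bars are SD (n = 2); the Dry libraries had the fewest genes, 10413 and 10664, and the highest shares, 93.5% and 94.6%.

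The libraries of a stage resembled each other more than those of any other stage. Across genes, the correlation of log2 CPM was between 0.884 and 0.945 within stages and between 0.572 and 0.915 between stages; genes are not independent replicates. Early and Late libraries stayed close to Hydrated, with mean correlations of 0.893 and 0.844. Dry libraries stood apart from Hydrated at 0.614 and from Late at 0.679. Rehydrated libraries were closer to Dry, at 0.817, than to Hydrated, at 0.625. The first principal component held 56.5% of the variance and separated Dry and Rehydrated from the other stages.

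**Figure D2:**
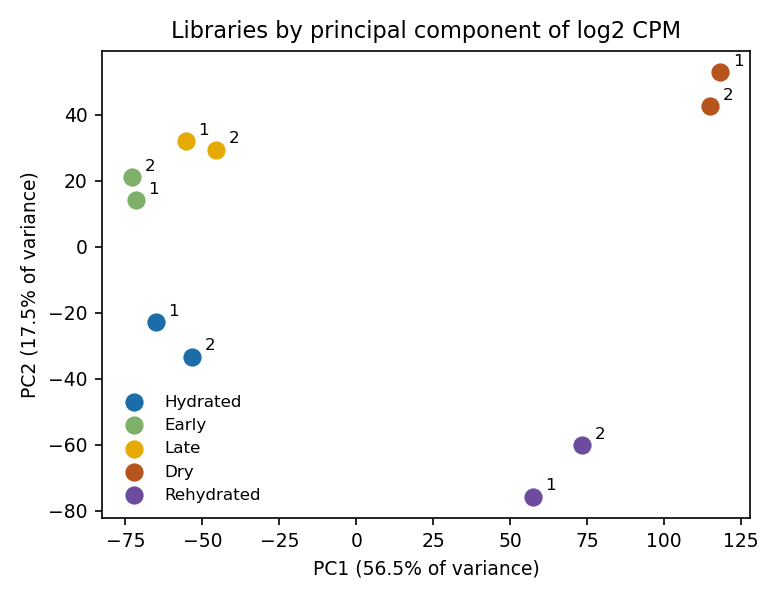
Principal components of log2 CPM over the 9856 genes tested, first component on the x axis (56.5% of variance) and second on the y axis (17.5%), with 1 point per library, coloured by stage and numbered by replicate. Libraries of a stage lie together, and Dry and Rehydrated lie to the right of the other stages.

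Of the 9856 genes tested, 5795 (58.8%) differed among the 5 stages in edgeR's quasi-likelihood F-test at an adjusted p of 0.05. Of these, 1821 had their highest mean in Dry, 1149 in Rehydrated, 1082 in Hydrated, 1012 in Early and 731 in Late. With library totals in place of TMM, the genes with their highest mean in Dry numbered 319 and those with their highest mean in Rehydrated 3345. Which genes passed the test, and so the split into higher and lower genes, depended on how libraries were scaled; the TMM factors lay between 0.403 in a Dry library and 1.99 in a Rehydrated library. Under TMM the median log2 fold change over all genes was -0.53 in Dry vs Hydrated and 0.45 in Rehydrated vs Dry; under library totals it was -2.29 and 2.28. The counts of higher and lower genes in each comparison are therefore followed by the number of genes called the same way under 4 scalings. No gene called one way under TMM was called the other way under another of the 4 scalings. A change of scaling shifts all fold changes of a comparison by nearly the same amount. Of the 4394 genes called in Dry vs Hydrated, 4370 differed at least 2-fold, so few could have reversed and their absence says little.

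**Figure D3:**
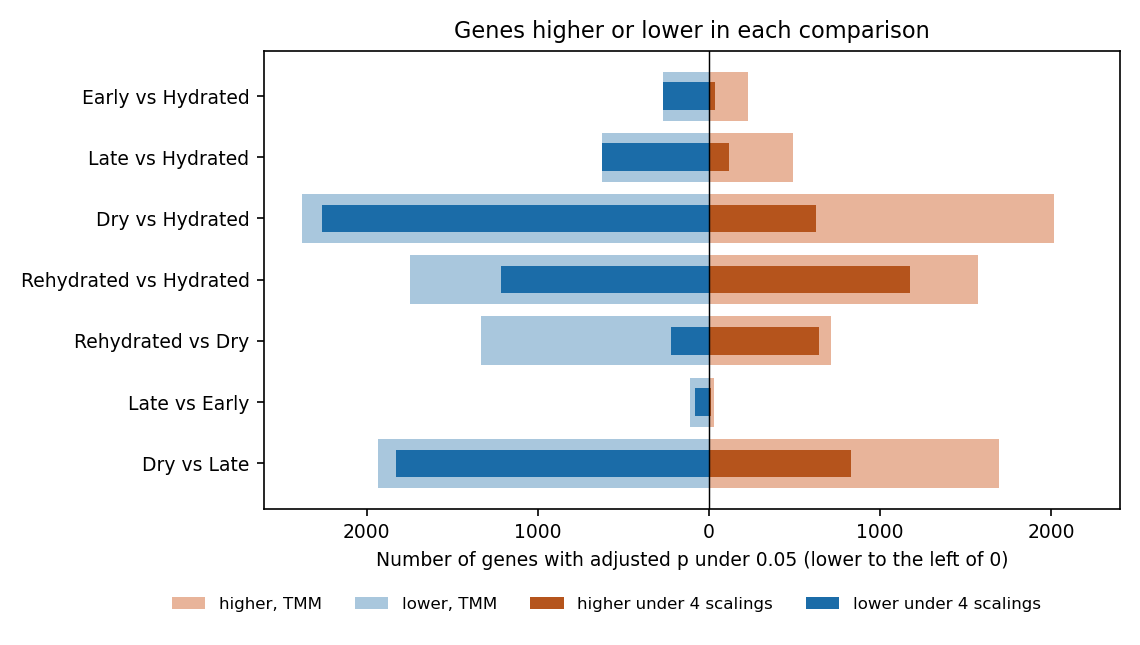
Number of genes (x axis) with an adjusted p under 0.05 in each comparison (y axis), higher to the right and lower to the left of 0. Wide pale bars show the TMM fit and narrow dark bars the genes called the same way under 4 scalings; in Dry vs Hydrated 623 of 2015 higher and 2259 of 2379 lower genes were called under each.

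The first question was what changed in the early phase of drying, at a volume loss of 25%. In Early vs Hydrated, 230 genes were higher and 269 lower, 5.06% of those tested, and 34 and 267 of them were called the same way under the 4 scalings. The largest rise was that of TRINITY_DN177542_c6_g2, from 1.84 ± 1.95 CPM (SD, n = 2) in Hydrated to 94.1 ± 38.8 in Early, a log2 fold change of 5.52 (SE 0.573, adjusted p = 7.34e-06). TRINITY_DN180306_c3_g2 rose from 11.4 ± 6.20 to 494 ± 161 CPM (log2 fold change 5.41, SE 0.553, adjusted p = 7.34e-06); its counts were not whole in 9 libraries, so part of its reads is shared with another assembled gene. TRINITY_DN178050_c2_g3 fell by 4.91 on the log2 scale, from 47.8 ± 12.4 to 1.51 ± 0.0194 CPM (SE 0.612, adjusted p = 7.21e-05). TRINITY_DN186231_c1_g2, an abundant transcript at 2516 ± 416 CPM in Hydrated, fell by 4.47 to 113 ± 34.1 CPM (SE 0.512, adjusted p = 3.0e-05); its counts were not whole in 6 libraries. With limma on log2 of the deposited signal plus 0.1, the calls of TRINITY_DN177542_c6_g2 and TRINITY_DN178050_c2_g3 were lost, at adjusted p of 0.0804 and 0.289, the highest over their alternatives. Without Hydrated replicate 1 the log2 fold changes of TRINITY_DN177542_c6_g2 and TRINITY_DN180306_c3_g2 were 7.39 and 6.12, and without Hydrated replicate 2 that of the former was 4.83. Of the 100 genes with the largest mean share of counts, a group chosen after the data were seen, 2 rose and none fell under TMM, while 1 rose and 2 fell under library totals. The main fit shares its estimate of the spread over all stages, and a fit of only these 2 stages gave 372 higher and 434 lower genes. The counts of this comparison rest on each of the 4 libraries: without Hydrated replicate 1, Hydrated replicate 2, Early replicate 1 or Early replicate 2 the higher genes numbered 70, 43, 92 and 57, and the lower genes 151, 75, 75 and 59.

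The late phase gave more changed genes than the early phase. In Late vs Hydrated, 491 genes were higher and 627 lower, and 117 and 627 of them were called under the 4 scalings. TRINITY_DN177542_c6_g2 reached 212 ± 43.2 CPM in Late (log2 fold change against Hydrated 6.68, SE 0.582, adjusted p = 2.62e-07). TRINITY_DN180306_c3_g2 reached 632 ± 89.5 CPM (log2 fold change 5.77, SE 0.562, adjusted p = 1.07e-06). With library totals the log2 fold changes of these 2 genes were 6.03 and 5.03, and without Hydrated replicate 1 8.56 and 6.48; that of the former was 6.0 without Hydrated replicate 2. For both, a difference between Early and Late did not pass the test (adjusted p = 0.247 and 0.866). TRINITY_DN186231_c1_g2 fell by 7.62 on the log2 scale, to 12.7 ± 2.06 CPM (SE 0.607, adjusted p = 6.92e-08), and was lower in Late than in Early (adjusted p = 0.00145); with library totals it fell by 8.39. TRINITY_DN171573_c6_g1, with 217 and 103 counts in the Hydrated libraries, had 1 count in the Late libraries together, a ratio of 173 under TMM and 297 under library totals (exact 95% Poisson intervals 30.8 to 6840 and 53.0 to 11800; adjusted p = 1.25e-06). Without Late replicate 2 the ratio was 80.9, and without Late replicate 1, which left 0 counts, it was at least 29.7-fold lower; its counts were not whole in 4 libraries. Between Early and Late, 29 genes were higher in Late and 113 lower, of which 9 and 83 held under the 4 scalings. Without Early replicate 1, Early replicate 2, Late replicate 1 or Late replicate 2 there were 7, 9, 15 and 7 higher genes, and without Rehydrated replicate 1 or 2, 54 and 53. Without Late replicate 2 there were 17 lower genes, without Late replicate 1 52 and without Early replicate 1 53. In Late vs Hydrated, leaving out Hydrated replicate 1, Hydrated replicate 2, Late replicate 1 or Late replicate 2 gave 197, 218, 263 and 250 higher genes and 380, 383, 328 and 296 lower genes.

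The 2 largest rises between Early and Late were of genes that had been lower in Early than in Hydrated (adjusted p = 0.000426 and 0.00987). TRINITY_DN185164_c5_g1 was at 439 ± 29.8 CPM in Hydrated, 53.5 ± 23.9 in Early and 591 ± 26.2 in Late (Late vs Early log2 fold change 3.47, SE 0.456, adjusted p = 0.000108). TRINITY_DN182176_c4_g2 was at 31.5 ± 12.7 CPM in Hydrated, 5.43 ± 2.39 in Early and 110 ± 15.6 in Late (log2 fold change 4.26, SE 0.537, adjusted p = 6.04e-05). Both calls were lost with limma on log2 of the deposited signal plus 0.1, at adjusted p of 0.074 and 0.185, and that of TRINITY_DN182176_c4_g2 also with 1 added, at 0.0593. The 2 largest falls were of genes whose identifiers share the number after DN. TRINITY_DN171573_c8_g1 fell by 6.58 on the log2 scale, from 516 ± 120 CPM in Early to 5.37 ± 2.60 in Late (SE 0.62, adjusted p = 1.73e-06), and TRINITY_DN171573_c6_g1 went from 251 counts in the Early libraries to 1 in the Late libraries, a ratio of 203 (exact 95% Poisson interval 36.0 to 8030; adjusted p = 1.77e-06, or 0.178 with the deposited signal plus 0.1). Without Late replicate 2 this ratio was 95, and without Late replicate 1, which left 0 counts, the gene was at least 35.4-fold lower.

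Among the 7 comparisons and with all libraries kept, Dry vs Hydrated gave the largest number of changed genes, 4394. Without Dry replicate 1 it gave 3117 against 3245 in Rehydrated vs Hydrated, and without Hydrated replicate 1 3402 against 3521 in Dry vs Late. In Dry vs Hydrated, 2015 genes were higher and 2379 lower, 44.6% of those tested, and 623 and 2259 of them were called under the 4 scalings; under library totals alone the numbers were 623 and 5732. TRINITY_DN171044_c0_g1, with 3 and 6 counts in the Hydrated libraries, had 6359 and 5488 in the Dry libraries, a rise from 1.93 ± 1.22 to 8976 ± 526 CPM (log2 fold change 12.17, SE 0.739, adjusted p = 5.75e-10); with library totals the log2 fold change was 10.39, and without Hydrated replicate 2 12.91. TRINITY_DN187552_c0_g1 had 0 counts in both Hydrated libraries and reached 835 ± 33.7 CPM in Dry, at least 676-fold higher under TMM and at least 192-fold under library totals (adjusted p = 8.72e-10). TRINITY_DN184245_c7_g1, at 74.4 ± 7.43 CPM in Hydrated, had 0 counts in both Dry libraries and was at least 16.3-fold lower under TMM and at least 57.4-fold under library totals (adjusted p = 6.85e-07). TRINITY_DN171573_c6_g1 likewise had 0 counts in Dry and was at least 13.8-fold lower under TMM and at least 48.1-fold under library totals (adjusted p = 3.91e-07). Of the 100 most abundant genes, 75 rose, 1 fell and 24 did not pass the test, with a median log2 fold change of 1.71 under TMM, but 18 rose and 9 fell under library totals, with a median of -0.11. Without Dry replicate 1 the lower genes numbered 1584.

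The step from Late to Dry was compared in turn. In Dry vs Late, 1694 genes were higher and 1932 lower, and 828 and 1831 of them were called under the 4 scalings. TRINITY_DN177519_c1_g2 had 12 and 15 counts in the Hydrated libraries, and 1 count in the Late libraries together but 1305 in the Dry libraries, a ratio of 2640 under TMM and 1300 under library totals (exact 95% Poisson intervals 473 to 104000 and 233 to 51400; adjusted p = 2.16e-09). Without Late replicate 2 this ratio was 1240, and without Late replicate 1 the gene was at least 465-fold higher in Dry. TRINITY_DN175670_c2_g2 had 0 counts in both Late libraries and reached 271 ± 20.9 CPM in Dry, at least 120-fold higher under TMM and at least 55.8-fold under library totals (adjusted p = 5.76e-09); its counts were not whole in 8 libraries. TRINITY_DN173691_c7_g2 went from 374 counts in the Late libraries to 1 in the Dry libraries, a ratio of 185 under TMM and 375 under library totals (exact 95% Poisson intervals 33.0 to 7330 and 67.0 to 14900; adjusted p = 5.35e-08). Without Dry replicate 2 this ratio was 95.5, and without Dry replicate 1 the gene was at least 29.7-fold lower. TRINITY_DN184657_c4_g1 fell by 7.22 on the log2 scale, from 464 ± 14.0 to 3.04 ± 0.138 CPM (SE 0.573, adjusted p = 1.02e-08), and it fell by 8.25 with library totals. Without Dry replicate 1 the lower genes numbered 1251.

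**Figure D4:**
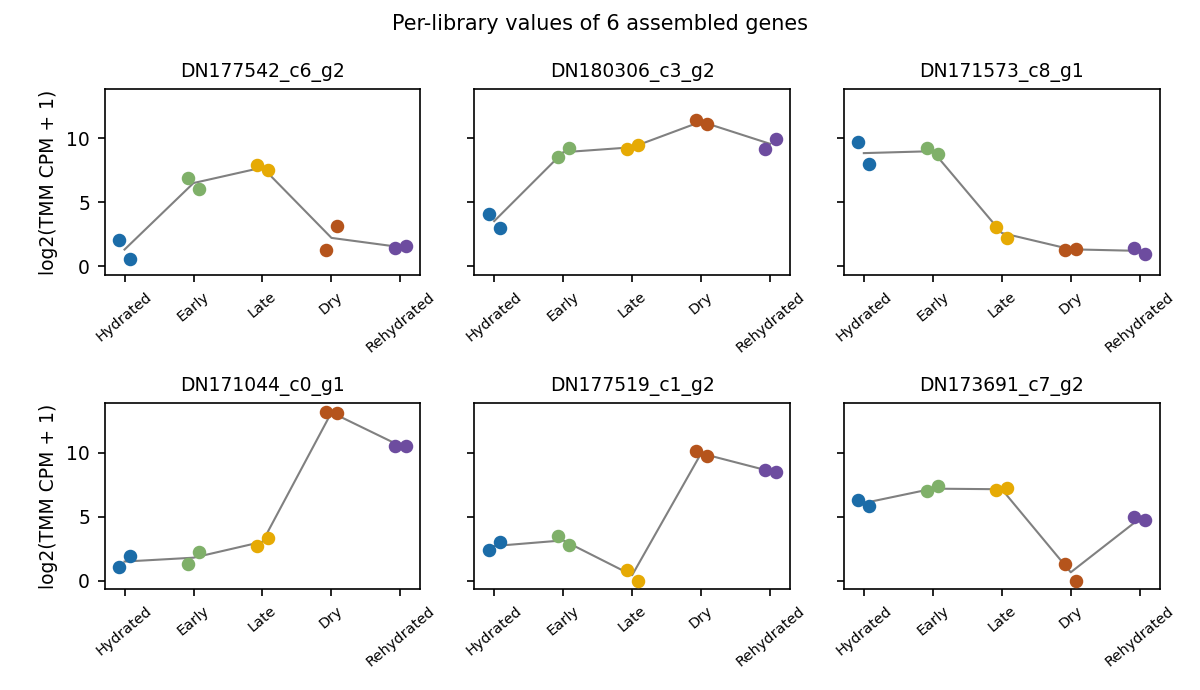
Expression of 6 of the named genes, picked for the plot after their values were seen to show different courses, as log2(TMM CPM + 1) on the y axis over the 5 stages on the x axis; points are libraries and grey lines join stage means. TRINITY_DN177542_c6_g2 was high in Early and Late alone, at 94.1 and 212 CPM, and TRINITY_DN171044_c0_g1 was high in Dry and Rehydrated, at 8976 and 1463 CPM.

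Overlaps between the stages were then counted. Of the 230 genes higher in Early than in Hydrated, 172 were also higher in Late and 94 in Dry; independent lists would share 11.5 and 47.0. Of the 269 lower genes, 193 were also lower in Late and 154 in Dry, against 17.1 and 64.9 for independent lists. Of the 491 genes higher in Late, 273 were higher in Dry, and of the 627 lower in Late, 454 were lower in Dry, against 100.4 and 151.3. Simulations without stage differences gave at most 1 shared gene, but called at most 4 genes in a comparison, so they do not measure what the shared libraries add to lists of this length. Among genes called under the 4 scalings, 30 of 34 higher and 192 of 267 lower Early genes were called the same way in Late, and 64 of 117 higher and 448 of 627 lower Late genes in Dry. These comparisons use the same Hydrated libraries, so part of the excess may come from the shared controls. In a check made after the data were seen, one comparison was fitted against each Hydrated library alone, both ways round. Early and Late then shared 20 and 45 higher and 57 and 66 lower genes, against 0.859, 1.55, 2.89 and 5.87 for independent lists. Early and Dry shared 13 and 22 higher and 47 and 67 lower genes, against 7.07, 12.2, 13.6 and 30.8. Late and Dry shared 131 and 107 higher and 279 and 242 lower genes, against 35.9, 34.3, 69.2 and 77.6.

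The last question was how far rehydration reversed the dry state within 1 h. In Rehydrated vs Dry, 713 genes were higher and 1330 lower, and 642 and 221 of them were called under the 4 scalings; under library totals the split was 5870 and 221. TRINITY_DN178348_c1_g1 rose from 45.5 ± 0.0747 CPM in Dry to 2388 ± 1600 in Rehydrated, having been at 9.92 ± 11.0 in Hydrated (log2 fold change against Dry 5.71, SE 0.905, adjusted p = 0.000107); the log2 fold change was 7.74 with library totals and 4.78 without Rehydrated replicate 1, and its counts were not whole in all 10 libraries. TRINITY_DN182300_c1_g2 rose from 3.14 ± 4.43 to 90.5 ± 3.77 CPM (log2 fold change 4.86, SE 0.72, adjusted p = 6.71e-05), but its Dry libraries held only 0 and 4 counts. Its log2 fold change was 6.71 with library totals, 3.90 without Dry replicate 1, and 10.13 without Dry replicate 2, which left 0 counts in Dry and so a value set by the model's prior count. TRINITY_DN185523_c3_g1, which was at 4.53 ± 0.836 CPM in Hydrated and 173 ± 45.4 in Dry, fell by 4.62 on the log2 scale to 7.25 ± 6.69 CPM (SE 0.533, adjusted p = 1.3e-05); the log2 fold change was -2.84 with library totals, -3.84 without Rehydrated replicate 1 and -6.06 without Rehydrated replicate 2. TRINITY_DN11536_c1_g2 had 0 counts in both Rehydrated libraries against 554 and 51 in Dry, at least 162-fold lower under TMM and at least 47.7-fold under library totals (adjusted p = 0.00585). The bound rests on Dry replicate 1 and was 29.0-fold without it and 295-fold without Dry replicate 2. Counts of this gene were not whole in 6 libraries, so part of its reads is shared with another assembled gene. How far its values of 0 come from that division was not tested. This gene also had 0 and 216 counts in Hydrated and 0 and 807 in Early, and its call was lost without Dry replicate 1 (adjusted p = 0.137), Rehydrated replicate 1 (0.0755) or Rehydrated replicate 2 (0.0604), with a mean of at least 50 counts (0.0579), and with limma on the deposited signal plus 1 (0.0548) or 0.1 (0.0913). Of the 100 most abundant genes, 1 rose and 70 fell under TMM, and 1 and 37 of them were called under the 4 scalings; under library totals 18 rose and 37 fell. Genes below the median share of counts in the other 9 libraries, a set chosen anew for each library, took 7.03% of the counts in Rehydrated replicate 1, against 2.64% in Rehydrated replicate 2, 1.75% and 2.65% in Hydrated and 0.634% and 0.704% in Dry. Without Dry replicate 1 there were 281 higher and 856 lower genes, and without Dry replicate 2 361 higher genes.

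Of the 2015 genes that were higher in Dry than in Hydrated, 1037 were lower in Rehydrated than in Dry, 51.5% (exact 95% binomial interval 49.3 to 53.7), and 1030 were still higher than in Hydrated. Of the 2379 genes that were lower in Dry, 501 were higher in Rehydrated than in Dry, 21.1% (19.4 to 22.8), and 1246 were still lower than in Hydrated. Genes that moved back and genes still changed are not complements. Of the genes higher in Dry, 407 were in both groups and 355 in neither, and of those lower in Dry, 134 and 766. These still-changed genes were 51.1% and 52.4% under TMM, but 80.9% (504 of 623) and 40.1% (906 of 2259) over genes called under the 4 scalings. Under TMM the median log2 fold change against Hydrated of the higher genes was 2.34 in Dry and 1.28 in Rehydrated. That of the lower genes was -2.88 and -1.4. The genes were chosen by their Dry values, which may add to this return. The shares of genes that moved back on rehydration, 51.5% and 21.1% above, depended on the scaling. Under library totals they were 15.4% and 72.2%. Over genes called under the 4 scalings they were 15.4% (12.7 to 18.5, 96 of 623) and 19.6% (18.0 to 21.3, 443 of 2259). These 2 values repeat the shares under library totals and under RLE factors, the shortest lists, and are no separate estimates. Over genes with a mean of at least 50 counts, which also changes the scaling, the shares were 46.8% and 52.1%. How easily a return could be called was not compared, so the shares do not rank the 2 directions. In simulations with no change on rehydration the shares were 0.0241% and 0.00999% on average over 20 data sets. Where no gene changes, almost none passes after adjustment, unlike in the data. These simulations therefore do not measure what the shared Dry libraries add to the shares. In the measured data, leaving out some single libraries moved these shares beyond the binomial intervals, which treat genes as independent. Without a Dry or Rehydrated library a return is also harder to call, so the shifts do not measure the spread between libraries alone. TRINITY_DN173691_c7_g2 rose on rehydration but stayed below its Hydrated level (adjusted p = 0.000102 and 0.0171). It had 211 and 122 counts in the Hydrated libraries, 1 and 0 in Dry and 37 and 25 in Rehydrated. TRINITY_DN184657_c4_g1 likewise rose and stayed below Hydrated (adjusted p = 0.00368 and 2.26e-07), at 408 ± 36.9 CPM in Hydrated, 3.04 ± 0.138 in Dry and 19.6 ± 0.464 in Rehydrated.

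At 1 h after rewetting, gene expression still differed from the hydrated start. In Rehydrated vs Hydrated, 1570 genes were higher and 1748 lower, and 1172 and 1214 of them were called under the 4 scalings. Of the genes higher in Rehydrated, 1030 had also been higher in Dry, and of those lower in Rehydrated, 1246 had been lower in Dry; independent lists would share 321 and 421.9, and simulations without stage differences, which called almost no gene, at most 1. Over genes called under the 4 scalings, 504 and 906 were shared, against 74.1 and 278 for independent lists. Part of this excess may come from the shared Hydrated libraries; with one comparison fitted against each Hydrated library alone, both ways round, 645 and 722 higher and 804 and 875 lower genes were shared, against 138, 194, 224 and 243 for independent lists. TRINITY_DN187552_c0_g1, with 0 counts in both Hydrated libraries, was at 162 ± 41.7 CPM and at least 131-fold higher (adjusted p = 1.66e-08). TRINITY_DN171044_c0_g1 was at 1463 ± 51.1 CPM (log2 fold change 9.55, SE 0.684, adjusted p = 4.75e-09; 10.29 without Hydrated replicate 2). TRINITY_DN181425_c3_g1 went from 103 ± 82.7 CPM in Hydrated to 0 counts in both Rehydrated libraries, at least 37.3-fold lower (adjusted p = 1.88e-06; at least 16-fold without Hydrated replicate 1 and 58.5-fold without Hydrated replicate 2), and TRINITY_DN182174_c3_g5 from 69.5 ± 21.2 CPM to 0 counts, at least 25.2-fold lower (adjusted p = 1.37e-07). The 100 most abundant genes were divided, with 21 higher, 18 lower and 61 not past the test; under library totals 25 were higher and 31 lower. Rehydrated replicate 1, with 7.03% of its counts in weakly expressed genes as above, and Hydrated replicate 2 were left out together in an alternative added after the data were seen, which gave 1037 higher and 1096 lower genes. Without Hydrated replicate 1 there were 791 higher and 1095 lower genes.

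Fold changes were compared with gene length. Across the 9856 genes, the Spearman correlation of the log2 fold change with relative length was -0.0779 in Early vs Hydrated, -0.0675 in Late vs Hydrated, 0.0274 in Dry vs Hydrated, 0.0685 in Rehydrated vs Hydrated and 0.0475 in Rehydrated vs Dry; over alternatives, with single libraries left out or over genes with a mean of at least 50 counts among them, it lay between -0.134 and -0.0468, -0.0876 and -0.0314, -0.0978 and 0.0477, 0.049 and 0.083, and 0.00769 and 0.235, in the same order. Genes with a non-whole expected count in any library made up 15.0% of the genes tested and 17.4% of those called in Dry vs Hydrated. The highest shares were among those called in Late vs Early (26.8%) and Early vs Hydrated (21.0%).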

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

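The 4 scalings, the TMM factors from genes with a mean of at least 50 counts and the removal of 2 libraries in doubt were chosen after seeing the data; the other alternatives were planned. Of the 613 values of named genes under alternatives, none reversed and 12 lost their call, 6 of them of TRINITY_DN11536_c1_g2. Named genes were picked from these same data for the largest changes, with absolute log2 fold changes of at least 3.47. The absence of reversals therefore does not tell how stable typical calls are. The tests of gene lists and their alternatives were not run, since identifiers have no names here. RLE factors, removal of the 100 most abundant genes and a fold-change threshold of 1 kept each count of genes within 1.5 times. The replicate number as a block moved no count of genes by over 1.5 times and gave 54.6% for the share of genes higher in Dry that fell on rehydration (51.5% without the block). It raised the called genes in each of the 7 comparisons, from 499 to 645 in Early vs Hydrated and from 142 to 189 in Late vs Early. Deviations of same-numbered libraries from their stage means correlated between -0.081 and 0.15 over the 10 pairs of stages, over 0.1 in 2. The numbers were not taken to pair libraries, but a weak effect of the replicate number stays open. Direction splits depended on scaling. With library totals, Early vs Hydrated had 34 higher genes, Late vs Hydrated 117 higher and 1347 lower, Dry vs Hydrated 623 and 5732, Rehydrated vs Dry 5870 and 221, Late vs Early 9 higher, and Dry vs Late 828 and 3585. Highest means then fell in Hydrated for 2818 genes, Late for 396, Dry for 319 and Rehydrated for 3345, and the recovery shares of genes higher and lower in Dry were 15.4% and 72.2%. With TMM factors from genes with a mean of at least 50 counts, Early vs Hydrated had 68 higher and 739 lower, Late vs Hydrated 189 and 1257, Dry vs Hydrated 1138 and 4245, and Rehydrated vs Dry 3286 and 553. Highest means fell in Hydrated for 2275, Early for 572, Dry for 926 and Rehydrated for 2549 genes, with shares of 29.6% and 52.7%. Genes called under the 4 scalings numbered 34, 117 and 623 higher in Early, Late and Dry vs Hydrated, 221 lower in Rehydrated vs Dry, 9 higher in Late vs Early and 828 higher in Dry vs Late, with a share of 15.4% for genes higher in Dry. Restricting to a mean of at least 50 counts tested 1932 genes, which itself lowers counts: Early vs Hydrated had 45 higher, Late vs Hydrated 128 and 399, Dry vs Hydrated 573 and 783, Rehydrated vs Hydrated 527 and 776, Rehydrated vs Dry 447 lower, and Dry vs Late 539 and 703. In all 1645 genes differed, with highest means in Hydrated for 469, Early 199, Late 166, Dry 500 and Rehydrated 303, and shares of 46.8% and 52.1%. Without a filter there were 181 lower genes in Late vs Early and a share of 14.0% for genes lower in Dry. DESeq2 gave 135 lower in Early, 377 in Late and 1553 in Dry vs Hydrated, 318 higher in Rehydrated vs Dry, 47 higher in Late vs Early, 1266 lower in Dry vs Late and a share of 14.8% for genes lower in Dry. Fits of only the 2 stages gave 372 higher and 434 lower in Early vs Hydrated and 50 higher in Late vs Early. limma on log2 of the deposited signal plus 1 gave 9 and 18 in Early vs Hydrated, 174 and 324 in Late vs Hydrated, 928 higher in Rehydrated vs Hydrated, 1466 higher in Rehydrated vs Dry, 4 and 26 in Late vs Early, and shares of 43.4% and 31.1%. With 0.1 added in place of 1 it gave 2 and 4, 110 and 150, 1272 higher in Dry vs Hydrated, 547 and 1141 in Rehydrated vs Hydrated, 883 lower in Rehydrated vs Dry, 2 and 14 in Late vs Early, highest means in Dry for 1169 and Rehydrated for 520 genes, and shares of 41.0% and 30.7%. Without Rehydrated replicate 1 and Hydrated replicate 2 there were 81 and 100 in Early vs Hydrated, 417 lower in Late vs Hydrated, 1037 and 1096 in Rehydrated vs Hydrated, 410 higher in Rehydrated vs Dry, 51 higher in Late vs Early, 635 genes highest in Rehydrated, and shares of 37.2% and 13.9%. Leaving out each library in turn, which assumes that the lone library of a stage varies like the others, gave ranges of 43 to 327 higher and 59 to 359 lower in Early vs Hydrated, 197 to 693 and 296 to 739 in Late vs Hydrated, 1584 to 2506 lower in Dry vs Hydrated, 791 to 1638 and 1095 to 1746 in Rehydrated vs Hydrated, 281 to 790 and 856 to 1347 in Rehydrated vs Dry, 7 to 54 and 17 to 143 in Late vs Early, and 1251 to 2077 lower in Dry vs Late. The genes highest in Rehydrated ranged from 757 to 1166 and the shares from 37.8% to 55.9% and from 13.4% to 22.0%. Without Rehydrated replicate 2, 757 genes had their highest mean in Rehydrated. Without Dry replicate 1 the share of genes lower in Dry that rose was 13.4%. Over genes with a mean of at least 50 counts the length correlation was -0.134 in Early vs Hydrated, -0.0978 in Dry vs Hydrated and 0.235 in Rehydrated vs Dry; it was -0.0468 in Early vs Hydrated without Early replicate 2, -0.0314 in Late vs Hydrated without Late replicate 1, and 0.0477 in Dry vs Hydrated and 0.00769 in Rehydrated vs Dry without Dry replicate 1. Apart from the smaller number of genes tested or libraries left, the cause of these shifts was not tested. The depth at which a gene is seen depends on scaling. With totals over the genes tested, 3 counts are worth 4.41 and 4.70 CPM in Dry under TMM. Under library totals, also over the genes tested, they are worth 5.0 and 3.72 CPM in Rehydrated. These are the highest values under each scaling.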

Other observations

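Some genes had 0 counts in both libraries of a stage, which does not show their absence at this depth. In Dry vs Hydrated, 322 of the lower genes had 0 counts in both Dry libraries, 311 of them called under the 4 scalings; 3 counts are worth 4.41 and 4.70 CPM there under TMM. In Rehydrated vs Hydrated, 63 of the lower genes had 0 counts in both Rehydrated libraries, 59 of them called under the 4 scalings. Of the 19 tested genes with 0 counts in both Hydrated libraries, 13 were higher in Dry and 14 in Rehydrated, 11 and 14 of them under the 4 scalings, TRINITY_DN187552_c0_g1 among them. The filter on counts keeps such a gene only where other libraries hold enough counts, so these shares are partly fixed by the filter. The same holds for the 484 tested genes with 0 counts in both Dry libraries, of which 128 were higher in Rehydrated than in Dry, 120 of them under the 4 scalings.

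Of the tests below, those on Rehydrated replicate 1 and on background reads in Hydrated were chosen or revised after the results were seen; those on abundant genes and on assembly components were written down before. Rehydrated replicate 1 stood apart: genes below the median share of counts in the other 9 libraries, a set chosen anew for each library, took 7.03% of its counts; with 1 set for all, chosen over the 10 libraries, it was 6.23% here and at most 2.50% elsewhere. An even background of reads over all assembled genes, such as genomic DNA, is a candidate explanation. Among those weak genes, the Spearman correlation of count and relative length was 0.445 in this library and at most 0.266 in the others, the highest being Rehydrated replicate 2. This library also held the most counts in weak genes. With these thinned to 9208 in each library the correlations were 0.275 and at most 0.206, so part of the distance came from the number of counts. Over all genes the correlation was 0.547 in this library and between 0.35 and 0.489 in the others, so counts rose with length in every library. The correlation of weak genes therefore cannot tell such a background apart from expression. With every library thinned to 644686 counts the share was 7.03% here and at most 2.69% in any draw of another library. Random thinning keeps the expected share of a set of genes, so this outcome was fixed in advance and decides nothing about depth. The Rehydrated replicates differed by 4.39 percentage points in this share against at most 0.904 in other stages, which restates the pattern, so an effect of the stage in this sample stays open and was not tested.

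At equal depth, 16698 genes were detected in Hydrated and 10539 in Dry. The 100 most abundant genes taking up the counts could not account for the whole gap. Without them, at 382058 counts, the gap was 73.1% of that at 644686 counts with all genes and 72.2% of that at 382058 counts with all genes. The 1000 most abundant genes took 94.0% of the counts in Dry and 80.3% in Hydrated, so a part of abundant genes beyond the 100 stays open. Background reads in the Hydrated libraries cannot be told apart from expression for this purpose: the length correlation of weak genes was 0.0747 in Hydrated replicate 1, below 0.128 and 0.221 in Dry, but 0.262 in Hydrated replicate 2. With weak genes thinned to equal counts it was 0.0428 and 0.154 in Hydrated and 0.129 and 0.204 in Dry, which leaves the stages overlapping. A narrower transcript pool in dried cells, whether from less transcription or from loss of RNA, may contribute, and the data do not separate these.

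Assembled genes whose identifiers share the number after DN, here called a component, tended to move together, which matters for reading counts of genes. Among the 4394 genes called in Dry vs Hydrated, 1073 shared a component with another, and 87.4% of their 894 pairs moved the same way, against at most 55.5% in 1000 shuffles (permutation p = 0.001, the smallest these shuffles can give). Reads divided between members are argued against as the whole cause, since 80.5% of the 395 pairs among genes with whole counts moved the same way, against at most 58.2% in shuffles. Pairs that also shared the number after c moved the same way in 96.7% of 272 cases and the others in 83.3% of 622, but among genes with whole counts in 88.4% of 43 and 79.5% of 352, so divided reads may account for part of the first difference. Such genes may be parts or copies of one transcript, in which case the 4394 calls correspond to at most 3786 components; related genes with a shared regulation stay open.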
